A study of Homo sapiens with 12 samples.

How the data were processed

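RNA-seq read counts were analysed for 12 libraries from a pair of human gastric cancer cell lines, MKN28 and MKN45. Each of the 4 groups held 3 libraries: MKN28 cells with a control lentivirus, MKN28 cells with ZNF165 knocked down, MKN45 controls, and MKN45 cells overexpressing ZNF165. Groups and replicate numbers were taken from the labels. The descriptions of knockdown replicates 2 and 3 name ZNF166 and ZNF167 in place of ZNF165, while their genotype field gives a ZNF165 knockdown, and the genotype field was followed. The gene listed today under the older name ZNF167, ZKSCAN7, had at most 1 count in any library, controls included, so a knockdown of it could not be seen. The labels do not say whether replicates were separate cultures, so every p-value measures the spread between these libraries, which may be technical.

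The deposited table holds whole-number read counts per Ensembl gene, 1 column per library, per the file headers and the values themselves. HISAT2, a spliced aligner, and StringTie, a transcript assembler and quantifier, were used per the submitters' processing notes, with no versions. The counting step, genome build, annotation and strand setting are not given in the sources used here. StringTie can export counts estimated from coverage, and whether the authors did so is not stated, so the counts may carry the rounding of such an estimate. With the strand setting unknown, reads of a gene and of an antisense or overlapping neighbour cannot be told apart, and the same holds for read-through transcripts, pseudogenes and near-identical paralogs. All sample columns were used.

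The table listed 50868 gene identifiers, of which 20369 had no count in any library. Symbols were found for 49659 identifiers in the gene name table, and 50111 identifiers were present in GENCODE 29, which supplied biotype, transcript length, GC content and GRCh38 coordinates. The authors' annotation release is not stated, so coordinates are those of GENCODE and not of the deposited table. A set of 11 identifiers carried a count of 1 in all libraries.

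Library totals ranged from 12075813 to 19548445 counts. A gene with 0 counts in a library could have had a level of up to 0.248 CPM (the count over the scaled library total) in the shallowest library and 0.153 CPM in the deepest, the level of 3 counts. Such floors cover counting error only, as reads carried no molecular identifiers. The spread between replicates was far above counting error: the chi-square of replicate pairs per degree of freedom was 21.2 to 460 where counting error alone gives a value near 1. Pearson correlations of log2 CPM between replicates, across genes, were 0.922 to 0.975 in MKN28 controls, 0.854 to 0.976 in knockdown libraries, 0.913 to 0.971 in MKN45 controls and 0.976 to 0.984 in overexpression libraries. CPM values in the text were scaled by TMM factors within the comparison they belong to, and their errors are standard deviations over 3 libraries. Exceptions, by unscaled library totals, are the floors above, the correlations between replicates, and values stated as unscaled. So are the values and minimum levels of genes listed at 0 or silent over all 6 libraries of a line.

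The tests were set before the data were examined, on the assumption of an FPKM or TPM table. The table turned out to hold counts, so the branch written for counts was used: edgeR's quasi-likelihood test with TMM normalization, genes kept by filterByExpr (minimum count 10, minimum total 15), and Benjamini-Hochberg adjusted p under 0.05. The knockdown (MKN28) and the overexpression (MKN45) were each fitted on the 6 libraries of their own line. The control libraries of both lines were compared in a separate fit. A fit of all 12 libraries tested whether the effect of higher against lower ZNF165 differed between lines. With its sign convention, that contrast equals the sum of the knockdown and overexpression log2 fold changes, so it is 0 for a gene that moves by equal amounts in opposite directions. Overlaps of genes past the threshold in both arms were tested with Fisher's exact test (two-sided), and the arms share no library. ZNF165 was also tested alone with an exact two-sided permutation test, for which 10 splits of 3 against 3 give a smallest possible p of 0.1.

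A set of 35 gene lists was fixed before the data were examined and tested with limma camera at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over lists. For members of a list, counts are given over all genes tested and adjusted over the list alone. ZNF165 was in no list. Of the 35 lists, 32 had enough tested members in the knockdown and 33 in each other comparison.

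The genes named in the text follow a rule set in advance. They are ZNF165; up to 8 rising and 8 falling genes per arm with the largest fitted fold changes among those past the threshold, with an absolute log2 fold change of at least 1, all treated libraries on one side of all controls, a symbol and a group mean of at least 5 CPM; up to 3 members of each of the 6 lists with the smallest camera p per arm, in the direction of the list; immune genes set in advance, of which CD274, HLA-B, B2M and CXCL10 are reported; 5 genes that passed in both arms with opposite signs; and, for the control lines, 5 rising and 5 falling genes. Where a group was at 0, the fold was computed against a floor of 3 counts over the group and is given as a lower bound. Some genes that the rule takes are not reported here. Genes named outside this rule are marked in the text as chosen after their values were seen.

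The edgeR tests of all 4 comparisons, and the set test in both arms, were tried on simulated counts drawn from the means, library sizes and fitted spread of the real libraries, with 200 genes changed, 50 per fold size, up to 16-fold in either direction. In the knockdown (14566 genes tested) 0% of the genes changed 2-fold were recovered, 10% of those changed 4-fold, 56% of those changed 8-fold and 94% of those changed 16-fold, with 4 unchanged genes among 84 calls. In the overexpression arm (15608 genes) the shares were 12%, 86%, 100% and 100%, with 10 unchanged genes among 159 calls. In the control lines (15801 genes) they were 4%, 72%, 100% and 98%, with 15 among 152 calls, and in the contrast between arms (16901 genes) 0%, 8%, 60% and 82%, with 3 among 78 calls. The 8-fold and 16-fold sizes were added after a first simulation with smaller changes recovered none in the knockdown. The set test called a list of 30 genes raised 2-fold in both arms and none of 40 unchanged lists. Simulated genes were drawn independently of each other, so this says nothing of false calls for lists whose members vary together. Nor did the simulation hold a difference shared by many genes of a library, which the real control libraries showed. Its share of unchanged genes among the calls is thus no error rate for the real calls. For ribosomal proteins the correlation estimated from the real libraries was 0.174 in the knockdown and 0.544 in the overexpression, above the preset 0.01. The overlap test, the permutation test and the set tests of the other comparisons were not simulated.

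Alternatives planned in advance were DESeq2 with its size factors, upper-quartile factors, no filter, a fold minimum, all 12 libraries in 1 fit, each library left out in turn, the replicate number as a block, and for lists the correlation estimated per list, fry, and voom with DESeq2 size factors. Chosen after seeing the data were the removal of a length and GC trend within each library (loess, span 0.5, entered as offsets), library totals alone, and leaving out knockdown replicates 2 and 3 together. The last leaves 1 knockdown library, which is assumed to vary like the other groups, so its p-values say little of the spread in the knockdown. Replicate numbers were checked for pairing by correlating deviations from the group means across genes. Between the control groups same-numbered libraries correlated at 0.264, 0.507 and 0.281, every pair above the 0.1 set as the rule. However, MKN28 control replicate 3 correlated with MKN45 control replicate 1 at 0.275, and MKN28 control replicate 1 with MKN45 control replicate 3 at 0.150. Replicates 1 and 3 were thus not told apart, so pairing by number is not shown, and the labels state no shared batch. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.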

Results

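RNA was sequenced from MKN28 and MKN45, established lines of human gastric adenocarcinoma cells, to compare cells with altered levels of ZNF165, a zinc-finger protein with a SCAN domain that is normally made mainly in the testis and is classed as a cancer/testis antigen. The series title places ZNF165 among possible targets of cancer immunotherapy, and genes of antigen presentation, interferon response and cytokine signalling were among the genes and lists chosen in advance. MKN28 control cells carried a control lentivirus and were compared with a ZNF165 knockdown, and MKN45 control cells were compared with a ZNF165 overexpression, with 3 libraries in each of the 4 groups. Single libraries held from 12075813 counts in knockdown replicate 3 to 19548445 in overexpression replicate 2.

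ZNF165 lay in the expected direction in every library of both arms. The gene (identifier ENSG00000197279, chromosome 6, 28080975 to 28089563, plus strand, GRCh38 in GENCODE 29) sits in the cluster of SCAN and zinc-finger genes on the short arm of that chromosome. In MKN28 its counts were 262, 186 and 287 in the controls and 74, 40 and 22 in the knockdown libraries. The level fell from 10.4 ± 2.31 to 3.74 ± 1.13 CPM, which is 36.0% of control (log2 fold change −1.47, SE 0.53, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0459). Without scaling between libraries the means were 13.9 and 2.99 CPM, a ratio of 0.215. In MKN45 the counts were 156, 140 and 277 in the controls and 2115, 1977 and 1909 in the overexpression libraries. The level rose from 12.2 ± 4.76 to 104 ± 6.198 CPM, an 8.50-fold increase (log2 fold change 3.09, SE 0.31, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0109). The counts do not tell a transgene from the endogenous gene. The exact two-sided permutation test gave p = 0.1 in each arm, the smallest p that 3 libraries against 3 allow. With knockdown replicates 2 and 3 left out together the knockdown did not pass (log2 fold change −1.09, adjusted p = 0.198 by the edgeR quasi-likelihood test), in a fit of 1 knockdown library whose spread is taken from the controls. It also did not pass when any library other than knockdown replicate 1 was left out, with edgeR adjusted p between 0.0116 and 0.173 over the libraries left out in turn. The overexpression call was likewise lost without overexpression replicate 1 (adjusted p = 0.0662) or replicate 2 (adjusted p = 0.0707, edgeR quasi-likelihood test), with a log2 fold change of 2.88 to 3.45 over the libraries left out in turn.

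**Figure D1:**
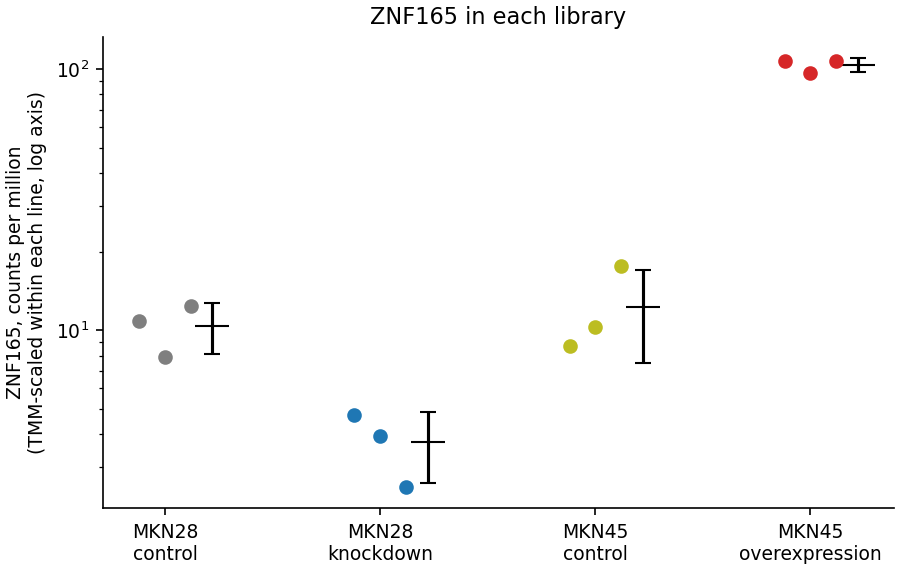
ZNF165 in each library, in CPM scaled by TMM within each cell line, on a log axis; points are single libraries and the bars give the mean and SD of 3 libraries. Knockdown libraries average 3.74 against 10.4 in MKN28 controls, and overexpression libraries average 104 against 12.2 in MKN45 controls.

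The libraries differed in composition as well as in ZNF165. Across genes, CPM correlated with transcript length at Spearman's rho of −0.171, −0.253 and −0.250 in knockdown replicates 1 to 3 and at 0.158, 0.0326 and 0.168 in their controls, so long transcripts were less abundant in the knockdown libraries. CPM correlated with GC content at 0.0949, 0.428 and 0.414 in the knockdown libraries and at −0.0605, 0.137 and −0.123 in their controls. In MKN45 the overexpression libraries lay at 0.159, 0.174 and 0.165 for length and −0.0920, −0.0999 and −0.132 for GC content. Control replicate 2 of MKN45 stood apart from its own group, at −0.0969 for length and 0.229 for GC content, against 0.0971 and 0.0324 for length and −0.0641 and −0.0319 for GC content in replicates 1 and 3. Genes are not independent replicates, so these correlations describe libraries. The knockdown libraries also had fewer genes with at least 1 count, 20560, 17620 and 17504, than their controls with 22579, 21102 and 22397. Mitochondrially encoded transcripts took 3.73 ± 1.28% of the counts in the knockdown against 6.32 ± 1.08% in MKN28 controls, and 12.7 ± 0.972% in the overexpression against 11.7 ± 2.26% in MKN45 controls (SD, n = 3).

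**Figure D2:**
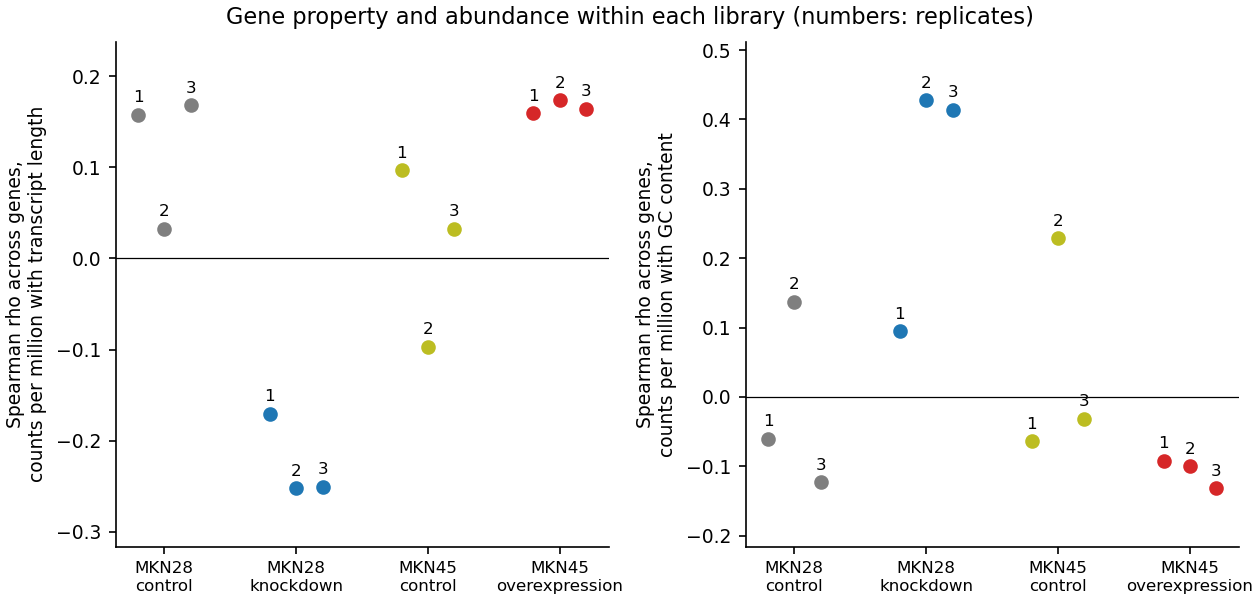
Spearman's rho across genes between CPM and transcript length (left) and GC content (right) in each of the 12 libraries, by group, with replicate numbers beside the points. Knockdown libraries lie lowest for length (−0.253 to −0.171), and control replicate 2 of each line lies above replicates 1 and 3 of its group for GC content.

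The knockdown comparison asks which genes change in MKN28 cells with less ZNF165. Genes of protein synthesis and of the respiratory chain were higher in the knockdown libraries. Of 34 cytosolic ribosomal protein genes, 25 rose, 0 fell and 9 did not pass the test (26 rose adjusted over the list alone), with a median log2 fold change of 2.02. RPL35, a component of the large ribosomal subunit, rose 15.9-fold from 441 ± 206 to 6999 ± 4955 CPM. RPS19, of the small subunit, rose 7.998-fold from 307 ± 100.8 to 2456 ± 1148 CPM, and RPLP0, of the ribosomal stalk, rose 7.27-fold from 614 ± 151 to 4465 ± 1957 CPM (SD, n = 3). Ribosomal protein genes have many processed pseudogenes, among which the counting could have split reads. Of 33 nuclear genes of oxidative phosphorylation, 21 rose, 0 fell and 12 did not pass (22 rose adjusted over the list alone), with a median of 1.86. COX5B and COX7B, subunits of cytochrome c oxidase, rose 9.48-fold and 7.06-fold, and NDUFA1, a subunit of complex I, rose 6.23-fold from 20.9 ± 2.49 to 130 ± 45.8 CPM. By camera the adjusted p was 1.79e-09 for ribosomal proteins and 1.28e-06 for oxidative phosphorylation. Neither call held with the correlation between genes estimated from the data (adjusted p = 0.451 and adjusted p = 0.398 with an estimated correlation). Both lists consist mainly of short transcripts. With the length and GC trend removed, both still passed camera at the preset correlation in the same direction. The median of the ribosomal proteins was 1.67, 1.94 and 2.41 in knockdown replicates 1 to 3 but also 0.50 in control replicate 2, all relative to the control mean.

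Replication-dependent histone genes, whose transcripts package newly made DNA and mostly lack a poly(A) tail, were higher as a group: 8 of 12 tested genes rose, 0 fell and 4 did not pass, the same counts as when adjusted over the list alone, with a median of 2.73. HIST1H3B, an H3 gene, rose from 0.0998 ± 0.0673 to 2.52 ± 0.882 CPM (23.6-fold), H1-2, a linker histone, from 13.2 ± 3.73 to 84.9 ± 20.3 CPM (6.44-fold), and H2AC8, an H2A gene, from 0.808 ± 0.212 to 6.63 ± 2.36 CPM (8.14-fold). Histone genes are near-identical copies, so values of single members are uncertain. The control mean of HIST1H3B also lay below the level of 3 counts per library, so its fold is not exact. Chemokines and inflammatory cytokines were also higher: 8 of 18 rose, 2 fell and 8 did not pass (10 rose and 2 fell adjusted over the list alone), with a median of 1.69. IL23A, the p19 subunit of interleukin 23, rose 32.1-fold from 1.61 ± 0.812 to 51.8 ± 17.8 CPM. CXCL3, a neutrophil attractant, rose 17.3-fold and CCL5, which attracts T cells, rose 9.06-fold from 42.2 ± 24.0 to 382 ± 49.4 CPM. CX3CL1 and CCL22, the members that fell, had log2 fold changes of −3.43 and −2.97 and were named after their values were seen. The camera adjusted p was 0.000996 for histones and 0.0473 for chemokines (adjusted p = 0.398 and adjusted p = 0.451 with an estimated correlation). The histone call ended when the length and GC trend was removed (median 1.01, adjusted p = 0.262), as did the calls of H1-2 and H2AC8. The chemokine call ended without control replicate 1 (median 1.46, adjusted p = 0.0580), control replicate 3 (1.47, adjusted p = 0.129) or knockdown replicate 1 (0.85, adjusted p = 0.141), with the replicate number as a block (1.56, adjusted p = 0.0637) and with voom on DESeq2 size factors (adjusted p = 0.0524).

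Antigen presentation genes moved less clearly. Of 6 tested MHC class II genes 4 rose, 0 fell and 2 did not pass (4 rose adjusted over the list alone), with a median of 1.75. Of 17 MHC class I genes 7 rose, 0 fell and 10 did not pass (7 rose adjusted over the list alone), with a median of 1.17. Neither list passed camera (adjusted p = 0.0717 for each). HLA-DRB1, the class II beta chain, rose 4.91-fold from 16.3 ± 5.52 to 79.9 ± 30.3 CPM. IFI30, a lysosomal reductase, rose 3.24-fold and HLA-DMA, which loads class II molecules, rose 3.49-fold. Of the class I genes PSMB10, an immunoproteasome subunit, rose 7.82-fold, HLA-E, a ligand of inhibitory receptors on natural killer cells, rose 4.51-fold, and HLA-B rose 3.67-fold (adjusted p = 0.0229, edgeR quasi-likelihood test). With the length and GC trend removed HLA-B (log2 fold change 0.54, adjusted p = 0.170) and HLA-DMA (1.22, adjusted p = 0.0516, edgeR quasi-likelihood test) did not pass, and with library totals alone IFI30, HLA-DMA, HLA-E and HLA-B did not pass (0.78, 0.90, 1.29 and 1.01, adjusted p of 0.0545 to 0.169, edgeR quasi-likelihood test). With single libraries left out, the calls ended for HLA-DMA without any library other than knockdown replicate 1 (edgeR adjusted p of 0.0562 to 0.144). They ended for IFI30 (0.0622 to 0.112) and HLA-B (0.0584 to 0.118) without control replicate 1 or 3 or knockdown replicate 2 or 3, for HLA-E without control replicate 1 (0.0816) or 3 (0.0752), and for HLA-DRB1 without control replicate 1 (0.0501). None of the 6 passed with replicate 1 as the lone knockdown library (adjusted p of 0.0505 to 0.346, edgeR quasi-likelihood test), a fit that takes the spread from the controls and so says little of their stability. HLA genes share sequence, so reads could have been split among them. CD274, which encodes the checkpoint ligand PD-L1, had a log2 fold change of 0.38 (adjusted p = 0.705), B2M, the light chain of class I molecules, 0.84 (adjusted p = 0.445) and CXCL10, an interferon-induced chemokine, 0.02 (adjusted p = 0.989, edgeR quasi-likelihood test). B2M had 17157 counts in knockdown replicate 1 against 957 and 923 in replicates 2 and 3, and CXCL10 had 137 against 0 and 0. B2M passed as a fall without replicate 1 (log2 fold change −1.16, adjusted p = 0.0137) and as a rise with replicate 1 as the lone knockdown library (2.21, adjusted p = 0.00777, edgeR quasi-likelihood test). Without replicate 1 CXCL10 had 0 counts in the knockdown. CD274 passed with the length and GC trend removed (1.87, adjusted p = 0.0191), while its adjusted p over the other alternatives lay between 0.187 and 0.999 (edgeR quasi-likelihood test or DESeq2).

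Among single genes, the largest rises included PADI1, which converts arginine to citrulline in proteins and rose 75.3-fold from 0.797 ± 0.507 to 60.7 ± 22.9 CPM, and C6orf226, which rose 41.5-fold from 1.81 ± 0.896 to 75.3 ± 36.2 CPM. TEN1, a telomere-binding protein, rose 42.3-fold from 1.67 ± 0.564 to 71.2 ± 53.1 CPM and overlaps a read-through transcript. ATXN2-AS (58.1-fold), CEBPB-AS1 (58.0-fold), ST7-AS1 (44.2-fold) and MBTPS1-DT (54.5-fold) are antisense or divergent transcripts whose reads could belong to their neighbours. INO80B-WBP1, a read-through of neighbouring genes, went from 0 counts in every control to 33, 387 and 45 counts, at least 358-fold higher against a floor of 3 counts over the control group, but it also varied among MKN45 controls (256, 0 and 213 counts) and overexpression libraries (0, 0 and 123). The largest falls included those of KIF21A, a kinesin motor (19.5 ± 8.57 to 0.161 ± 0.2002 CPM, log2 fold change −6.66), KDM7A, a histone demethylase (−6.46), SYTL2 and RAB27B, which act in vesicle docking (−6.33 and −6.09), NBEA, a scaffold of vesicle traffic (−5.98), DPF3, a chromatin-remodelling subunit (−5.96), and TBC1D8B, a predicted regulator of Rab proteins (−5.93). MYO15B fell from 5.12 ± 3.42 CPM to 0 counts in every knockdown library, at least 58.8-fold lower against a floor of 3 counts over the knockdown group. For these genes the adjusted p lay between 0.00367 and 0.00495 (edgeR quasi-likelihood test, Benjamini-Hochberg), and all 3 knockdown libraries lay on one side of all controls. The named falls other than MYO15B rest on few counts in knockdown replicates 1 to 3, so their sizes are not exact. Those counts were 6, 1 and 0 for KIF21A, 3, 2 and 0 for KDM7A, and 2, 4 and 0 for NBEA. SYTL2, RAB27B and DPF3 each had 3, 0 and 0, and TBC1D8B had 4, 0 and 0. Among the rises, ATXN2-AS had 3 counts in each control, CEBPB-AS1 10, 0 and 2, and MBTPS1-DT 7, 17 and 0, so these folds are likewise not exact.

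Other lists did not pass in the knockdown. Of 20 NF-kB targets 6 rose, 2 fell and 12 did not pass (10 rose and 2 fell adjusted over the list alone), with a median of 1.33 and a camera adjusted p of 0.0717. Of 26 p53 targets 9 rose, 2 fell and 15 did not pass (10 rose and 2 fell adjusted over the list alone), with a median of 0.78 (adjusted p = 0.0873). Of 17 Wnt/beta-catenin targets 0 rose, 8 fell and 9 did not pass (9 fell adjusted over the list alone), with a median of −1.27 (adjusted p = 0.114). Of 36 interferon-stimulated genes 5 rose, 11 fell and 20 did not pass (5 rose and 14 fell adjusted over the list alone), with a median of −1.002 (adjusted p = 0.143). The median was −0.48 in knockdown replicate 1 against −2.38 and −2.22 in replicates 2 and 3. Of 12 SCAN and zinc-finger genes that neighbour ZNF165, 0 rose, 5 fell and 7 did not pass (5 fell adjusted over the list alone), with a median of −1.02 (adjusted p = 0.144) and medians of −0.16, −2.22 and −2.54 in replicates 1 to 3. Immune checkpoint ligands had a median of 0.02 (1 of 17 rose and 2 fell, adjusted p = 0.852), and cancer/testis antigens other than ZNF165 a median of 0.41 (4 of 17 rose and 4 fell, adjusted p = 0.842).

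In all, 6092 of 14939 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2864 higher and 3228 lower, so 47.0% were higher. The groups did not overlap at 8040 genes (53.8%), where chance gives 10%. With genes in 4 equal groups by transcript length, the shortest had a median log2 fold change of 1.05 and the longest −1.63, against −0.20 for all genes tested. That all-gene median was −0.28 with upper-quartile factors, −0.92 with library totals alone and −0.06 with DESeq2. The share of higher genes was 25.1% with library totals alone and 59.0% with the length and GC trend removed, when 6194 genes passed, of which 3910 were among the 6092. The count was 3352 with replicate 1 as the lone knockdown library, 2642 without control replicate 1, 3171 without control replicate 3 and 10378 without knockdown replicate 1.

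The overexpression comparison asks which genes change in MKN45 cells with more ZNF165. Immediate early genes, which respond to growth factor and stress signals within minutes, were higher: 4 of 30 rose, 0 fell and 26 did not pass (9 rose adjusted over the list alone), with a median log2 fold change of 0.60. EGR1, a zinc-finger transcription factor, rose 3.74-fold from 196 ± 38.6 to 733 ± 143 CPM, its relative EGR3 rose 6.97-fold from 3.23 ± 0.131 to 22.5 ± 8.92 CPM. FOSB, a subunit of AP-1, rose 6.43-fold from 7.17 ± 3.31 to 45.9 ± 10.96 CPM, and NR4A2, an orphan nuclear receptor, rose 6.04-fold from 3.01 ± 1.19 to 18.1 ± 3.20 CPM (SD, n = 3). Their adjusted p lay between 0.0186 and 0.0207 (edgeR quasi-likelihood test). None of these 4 passed without control replicate 3, without any 1 of the overexpression libraries or in the fit of all 12 libraries, and with the replicate number as a block only FOSB passed. NFKBIZ, an inducible co-regulator of NF-kB target genes, had the largest rise among the named genes, 15.7-fold from 0.915 ± 0.0379 to 14.4 ± 2.78 CPM (adjusted p = 0.00437, edgeR quasi-likelihood test). It passed under every alternative run and was the only gene of the comparison to pass without overexpression replicate 1 or replicate 2. Of 28 p53 targets 3 rose, 0 fell and 25 did not pass (7 rose adjusted over the list alone), with a median of 0.35, which was 0.18 without control replicate 2 and 0.20 with the length and GC trend removed. PLK2, a kinase, CDKN1A, an inhibitor of the cell cycle, and BTG2, an antiproliferative factor, were the members that rose, by 2.19, 1.17 and 1.83 on the log2 scale, and were named after their values were seen. Of 28 TGF-beta/SMAD targets 1 rose, 0 fell and 27 did not pass (6 rose adjusted over the list alone), with a median of 0.22. The member that rose, SKIL (log2 fold change 1.53, named after its value was seen), is a negative regulator of the pathway. The camera adjusted p was 0.000248 for immediate early genes, 0.00328 for p53 targets and 0.0162 for TGF-beta/SMAD targets (adjusted p = 0.583, adjusted p = 0.518 and adjusted p = 0.518 with an estimated correlation), and the last call ended without control replicate 3 (median 0.15, adjusted p = 0.0635). Of the 9 lists that camera called in the overexpression, fry called only p53 and TGF-beta/SMAD targets.

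Ribosomal protein genes were lower as a group in the overexpression libraries. Of 34 genes 0 rose, 2 fell and 32 did not pass over all genes, while 33 fell adjusted over the list alone, with a median of −0.92. RPS18 fell from 2278 ± 199 to 1075 ± 109 CPM (log2 fold change −1.08) and RPL35 from 684 ± 172 to 288 ± 7.26 CPM (−1.25), and RPL13A, with a log2 fold change of −1.12, did not pass (adjusted p = 0.0505, edgeR quasi-likelihood test). RPS18 and RPL35 did not pass without control replicate 3 or any 1 of the overexpression libraries, nor in the fit of all 12 libraries or with the replicate number as a block. Nuclear genes of oxidative phosphorylation had a median of −0.59 (−0.37 without control replicate 2), with 0 rising, 0 falling and 33 not passing (1 fell adjusted over the list alone). COX5B, UQCRQ of complex III and ATP5PO of the ATP synthase had log2 fold changes of −1.01, −0.90 and −0.77 (adjusted p of 0.0549 to 0.0858, edgeR quasi-likelihood test). The camera adjusted p was 4.05e-19 for ribosomal proteins and 2.67e-06 for oxidative phosphorylation (adjusted p = 0.583 for each with an estimated correlation). Relative to the control mean, the ribosomal median was −0.98, −0.94 and −0.79 in the overexpression libraries and −0.28, 0.34 and −0.01 in control replicates 1 to 3.

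Genes of hypoxia, glycolysis and amino acid supply were lower as groups. Of 25 hypoxia genes 0 rose, 2 fell and 23 did not pass (8 fell adjusted over the list alone), with a median of −0.66. SLC2A1, a glucose transporter, fell from 607 ± 158 to 235 ± 43.8 CPM (log2 fold change −1.37) and BNIP3, a mitochondrial protein that promotes mitophagy, fell from 226 ± 28.1 to 99.5 ± 10.3 CPM (−1.18), while EGLN3, an oxygen sensor, had a log2 fold change of −1.12 (adjusted p = 0.0508, edgeR quasi-likelihood test). Of 18 glycolysis genes 0 rose, 1 fell and 17 did not pass (7 fell adjusted over the list alone), with a median of −0.53, which was −0.28 without control replicate 2 and −0.35 with the length and GC trend removed. ALDOC, an aldolase, was the member that fell, from 174 ± 41.0 to 70.5 ± 2.64 CPM (−1.31), and PGK1 and ALDOA had log2 fold changes of −0.85 and −1.04 (adjusted p of 0.0594 and 0.0690, edgeR quasi-likelihood test). Of 26 ATF4 targets of the amino acid response 0 rose, 1 fell and 25 did not pass (4 fell adjusted over the list alone), with a median of −0.55 and medians of −1.10, −0.25 and −0.25 in overexpression replicates 1 to 3. NUPR1, a stress-induced nuclear protein, was the one that fell, from 98.0 ± 27.9 to 28.3 ± 10.004 CPM (−1.79), and SHMT2 of serine metabolism and WARS1, a tRNA synthetase, had log2 fold changes of −0.88 and −0.69 (adjusted p of 0.0772 and 0.0849, edgeR quasi-likelihood test). The camera adjusted p was 1.79e-05 for hypoxia and 0.000180 for both other lists (adjusted p = 0.583, and adjusted p = 0.708 for ATF4 targets, with an estimated correlation). Without overexpression replicate 1 the median was −0.43 for hypoxia genes and −0.34 for ATF4 targets. SLC2A1, BNIP3, ALDOC and NUPR1 did not pass without control replicate 3 or any 1 of the overexpression libraries, in the fit of all 12 libraries or with the replicate number as a block, and of these only ALDOC passed with library totals alone.

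MHC class I genes had a median of −0.59 with 0 rising, 0 falling and 21 not passing (1 rose and 6 fell adjusted over the list alone), and a camera adjusted p of 0.0164 (adjusted p = 0.583 with an estimated correlation). HLA-B had a log2 fold change of −0.85 (adjusted p = 0.119) and B2M one of −0.97 (adjusted p = 0.134), neither past the threshold of the edgeR quasi-likelihood test. The list's call ended with the length and GC trend removed (median −0.34, adjusted p = 0.0695) and in the fit of all 12 libraries (median −0.60, adjusted p = 0.0508). CD274 had a log2 fold change of 0.50 (adjusted p = 0.687, edgeR quasi-likelihood test) at 0.720 ± 0.637 CPM in controls and 1.05 ± 0.263 CPM with overexpression. CXCL10 was too low in MKN45 to be tested. Interferon-stimulated genes had a median of 0.00 (0 of 35 passed, adjusted p = 0.962) and gastric lineage genes one of 0.66 (1 of 15 rose, adjusted p = 0.0758). The gastric gene that rose, MUC5AC, a mucin of the stomach surface, had a log2 fold change of 1.44 and was named after its value was seen.

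Of the remaining single genes, LINC00342 (8.10-fold), MIR22HG (6.96-fold), N4BP2L2-IT2 (7.64-fold) and GABPB1-AS1 (7.42-fold) rose. The first pair are long non-coding RNAs, and the second pair lie within or opposite other genes, whose reads could be counted to them. ZNF696, a zinc-finger gene, fell from 11.7 ± 2.36 to 1.36 ± 0.228 CPM (log2 fold change −3.09, adjusted p = 0.0109, edgeR quasi-likelihood test). CIPC, a regulator of the circadian clock (−1.64), NT5M, a mitochondrial nucleotidase (−1.59), LINC02387 (−1.46), SDHAF4, an assembly factor of complex II (−1.45), and HJURP, the chaperone that loads CENP-A at centromeres (−1.44), also fell. ISY1-RAB43, a read-through transcript, went from 17.3 ± 8.93 CPM to 0 counts in every overexpression library, at least 333-fold lower against a floor of 3 counts over the group, but it also had 0 counts in 2 of the 3 MKN28 controls and in 1 of the 3 knockdown libraries. None of the genes of this paragraph passed without overexpression replicate 1 or replicate 2, or in the fit of all 12 libraries.

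In all, 179 of 15833 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 148 higher and 31 lower, so 82.7% were higher, while 4242 had an unadjusted p under 0.05. The groups did not overlap at 6037 genes (38.1%), where chance gives 10%. DESeq2 called 1834 genes, 56.6% of them higher, and 1334 passed with the length and GC trend removed, 46.0% of them higher. With no filter 722 passed, in the fit of all 12 libraries 3, and with the replicate number as a block 8. The count was 1 without overexpression replicate 1 or without replicate 2, 12 without replicate 3, 6 without control replicate 3, 591 without control replicate 1 and 1338 without control replicate 2.

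**Figure D3:**
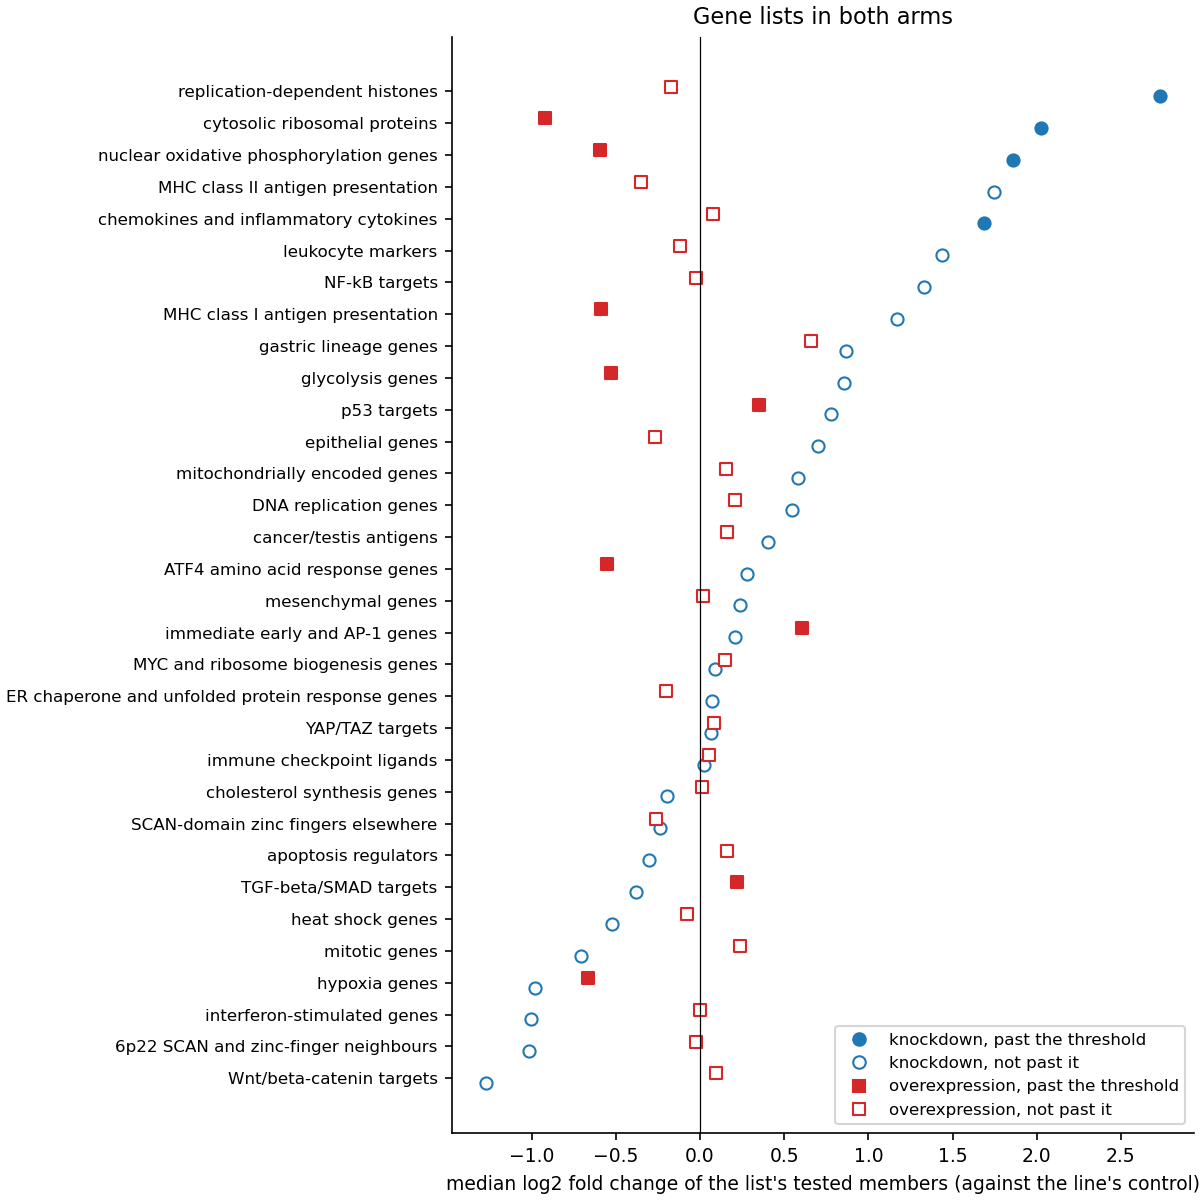
Median log2 fold change of the tested members of each gene list in the knockdown (blue circles) and the overexpression (red squares), each against its own control; filled symbols passed camera with the preset correlation. Ribosomal proteins lie at 2.02 in the knockdown and −0.92 in the overexpression, and hypoxia genes lie below 0 in both (−0.98 and −0.66).

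A further comparison asks whether the same genes follow ZNF165 in both lines. Of 13720 genes tested in both arms, 60 fell in the knockdown and rose in the overexpression, where independent calls would give 25.7 (odds ratio 3.82, Fisher's exact test, p = 2.80e-12, Benjamini-Hochberg adjusted p = 1.12e-11 over 4 overlaps). Another 9 rose in the knockdown and fell in the overexpression, where 4.60 would be given (odds ratio 2.5003, p = 0.0348 raw and adjusted, Fisher's exact test). Genes that moved the same way were fewer than independence gives, 8 rising in both against 21.3 (p = 0.000650, adjusted p = 0.00130) and 1 falling in both against 5.54 (p = 0.0276, adjusted p = 0.0348, Fisher's exact test). These p-values assume calls that are independent between arms when nothing acts on both, while the difference of control replicate 2 from replicates 1 and 3 correlated between the lines at r = 0.571 across genes, so they are no test of an effect of ZNF165. Ranked by the larger adjusted p of the arms, the first genes that moved in opposite directions were CATSPER2, a subunit of the sperm calcium channel (log2 fold change −5.08 in the knockdown and 2.11 in the overexpression), NPIPB5, a member of a nuclear pore-interacting protein family with near-identical copies (−2.54 and 1.85), EGR3 (−3.13 and 2.80), UVSSA, a factor of transcription-coupled repair (−2.77 and 2.08), and ZNF696 (2.99 and −3.09). CATSPER2 has a pseudogene copy that could share its reads. ZNF696 was not separated in the knockdown, with 31 counts in replicate 1 against 329 and 209 in replicates 2 and 3 and 46 to 71 in the controls. Across genes the fold changes of the arms correlated at Pearson's r = −0.545 and Spearman's rho = −0.598, and 72.7% had opposite signs, with genes not being independent replicates. Pearson's r was −0.345 without MKN45 control replicate 2. Over the alternatives run it lay between −0.594 (without MKN45 control replicate 1) and −0.238 (with no filter). The 69 genes with opposite signs became 0 without overexpression replicate 1 or replicate 2, 2 without overexpression replicate 3 or MKN45 control replicate 3, 42 without MKN28 control replicate 1, 43 without MKN28 control replicate 3, 318 without MKN45 control replicate 1 and 637 without MKN45 control replicate 2. They became 968 with DESeq2, 512 with the length and GC trend removed, 356 with no filter, 41 with knockdown replicates 2 and 3 left out, 2 in the fit of all 12 libraries and 2 with the replicate number as a block.

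**Figure D4:**
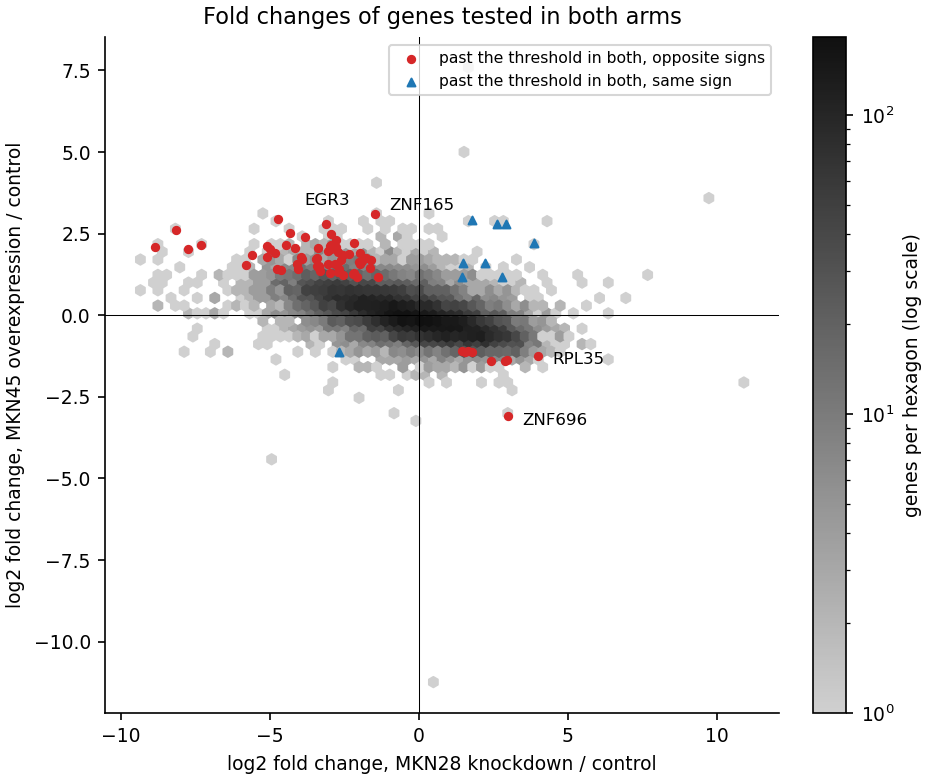
Log2 fold change in the knockdown (horizontal) and in the overexpression (vertical) for the 13720 genes tested in both, as hexagons shaded by the number of genes; red points passed in both with opposite signs (69 genes) and blue triangles in both with the same sign (9 genes). Most genes lie along a falling diagonal (Pearson's r = −0.545).

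A test of the difference itself gave 3017 of 17266 genes whose change with higher against lower ZNF165 differed between the arms (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The knockdown was made only in MKN28 (ZNF165 at 36.0% of control) and the overexpression only in MKN45 (8.50-fold). A difference between lines thus cannot be told apart from one between the manipulations or the sizes of the ZNF165 change. Ribosomal proteins had a median difference of 1.12 (32 of 34 above 0, camera adjusted p = 9.26e-05), oxidative phosphorylation genes 1.41 (26 of 33 above 0, 9.26e-05) and histones 1.97 (11 of 12 above 0, 0.000336), none of which held with an estimated correlation (adjusted p = 0.607, adjusted p = 0.541 and adjusted p = 0.409 with an estimated correlation). For these lists the knockdown changes were the larger. Of the 3017 genes 46.3% lay above 0, and 19.7% of 3121 did with library totals alone. The count was 1217 with knockdown replicates 2 and 3 left out, 4730 with DESeq2, and 1163 to 8210 over the libraries left out in turn. It was 1163, 3484 and 1353 without MKN45 control replicates 1 to 3, and 1272, 3291 and 1783 without MKN28 control replicates 1 to 3. It was 8210, 1941 and 1751 without knockdown replicates 1 to 3, and 1259, 1415 and 1417 without overexpression replicates 1 to 3.

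The control libraries show the baseline that each arm starts from. MKN45 had higher levels of most tested digestive lineage genes than MKN28: of 11 intestinal lineage genes 10 were higher in MKN45, 0 lower and 1 did not pass (the same counts adjusted over the list alone), with a median log2 difference of 8.66. Of 13 gastric lineage genes 11 were higher, 1 lower and 1 did not pass, with a median of 6.51. MKN28 had more interferon-stimulated and cancer/testis transcripts. Of 39 interferon-stimulated genes 23 were lower in MKN45, 5 higher and 11 did not pass (24 lower adjusted over the list alone), with a median of −1.96. Of 16 cancer/testis antigens 8 were lower, 1 higher and 7 did not pass, with a median of −1.12. The camera adjusted p was 1.13e-13, 2.35e-13, 2.30e-06 and 1.82e-05 for these lists. The gastric list held with an estimated correlation (adjusted p = 0.0407), while the others had adjusted p = 0.153 with an estimated correlation. MHC class I genes were higher in MKN45 (8 of 20 higher, 0 lower, 12 not passing, median 0.86, camera adjusted p = 0.000511, adjusted p = 0.700 with an estimated correlation). So were ribosomal proteins (21 of 34, 0 lower, median 1.16, adjusted p = 0.00295, adjusted p = 0.700 with an estimated correlation) and hypoxia genes (11 of 25 higher, 4 lower, median 1.05, adjusted p = 0.00487, adjusted p = 0.597 with an estimated correlation).

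Several genes were listed at 0 in every control library of one line. FOXJ1, the master regulator of motile cilia, had 324 ± 129 CPM in MKN45 controls and 0 counts in MKN28 controls (at least 5993-fold higher, against a floor of 3 counts over the group). BNIP3 (at least 4189-fold), CMBL, a hydrolase of the liver and gut (at least 4187-fold), ELOVL5, which elongates fatty acids (at least 3260-fold), and HEXA, a lysosomal enzyme (at least 2870-fold), were likewise seen in MKN45 controls and at 0 in MKN28 controls. In the other direction S100A9, a calcium-binding alarmin, lay at 173 ± 91.0 CPM in MKN28 controls and 0 in MKN45 controls (at least 2714-fold lower in MKN45). MAGEB2 and MAGEA12, cancer/testis antigens of the MAGE family, were at 131 ± 19.7 and 69.1 ± 13.8 CPM in MKN28 and 0 in MKN45 (at least 2048-fold and 1084-fold lower), and TENM3, an adhesion receptor of neurons, was at least 1777-fold lower. In all, 6717 of 16088 genes differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 3442 higher and 3275 lower in MKN45, and the groups did not overlap at 8410 genes (52.3%), where chance gives 10%. The lines come from different tumours, so no single cause can be assigned to a difference between them.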

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

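Chosen only after the result was seen were all 3 tests of the knockdown pattern, the overlap test of genes listed at 0, and the removal of the length and GC trend. The splits of the libraries and both tests of the opposite arms were set before their results were seen.

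These results stood out because the change with higher against lower ZNF165 differed between MKN28 and MKN45 in a test of the difference itself, whose value is 0 for equal and opposite changes in the arms. Only MKN28 had a knockdown and only MKN45 an overexpression, so line, kind of manipulation and size of the ZNF165 change cannot be told apart in this test. It passed for 3017 genes (edgeR quasi-likelihood test), among them ZNF165 at 1.67 (adjusted p = 0.0421), whose log2 fold change was −1.47 in the knockdown and 3.09 in the overexpression. By camera it passed for chemokines and inflammatory cytokines with a median difference of 1.80 (adjusted p = 0.0173; medians 1.69 in the knockdown and 0.08 in the overexpression) and for NF-kB targets with 0.93 (adjusted p = 0.0152; 1.33 and −0.02). It also passed for DNA replication genes with 0.75 (adjusted p = 0.0193; 0.55 and 0.21), p53 targets with 1.28 (adjusted p = 0.000385; 0.78 and 0.35) and hypoxia genes with −1.13 (adjusted p = 0.0193; −0.98 and −0.66). The others were nuclear oxidative phosphorylation genes with 1.41 (adjusted p = 9.26e-05; 1.86 and −0.59), ribosomal proteins with 1.12 (adjusted p = 9.26e-05; 2.02 and −0.92) and replication-dependent histones with 1.97 (adjusted p = 0.000336; 2.73 and −0.17). No list held with an estimated correlation, p53 targets coming nearest (adjusted p = 0.0588 with an estimated correlation), while fry called 4 of these lists, p53 targets, histones, oxidative phosphorylation and hypoxia genes, and 3 others, Wnt/beta-catenin targets, leukocyte markers and intestinal lineage genes.

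Within-line splits of the libraries gave as many genes differing between arms in 8 of 100, the real split included, so chance is not excluded for the 3017 by the rule set for it. All 8 kept the real knockdown groups, so the count followed the MKN28 groups and these splits are no random regrouping of that line. The 10 splits of MKN28 are too few for a share under 0.05, so this test cannot decide on chance. The highest other split gave 7402 genes and was the real one with the MKN45 groups exchanged. For the genes that passed in both arms with opposite signs 1 of 100 splits, the real one, gave as many as 69 and the highest other gave 9, but these splits decide nothing on the overlap. Every split other than the real groups called 0 genes in at least 1 line by edgeR, so no overlap could arise, and the 9 are the genes of the same sign with the MKN45 groups exchanged. Within a single comparison the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 with most genes in the knockdown (6092, highest other 0), in the overexpression (179, highest other 0) and between control lines (6717, highest other 0, all by edgeR). For gene lists, 9 of 10 splits gave as many as the 4 of the knockdown (highest other 11) and 4 of 10 as many as the 9 of the overexpression (highest other 13).

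Fold changes in the knockdown followed transcript length (Pearson's r = −0.479 across 13658 genes) and GC content (r = 0.498). Against that trend as the whole cause, 6194 genes passed once it was removed in each library, beside 6092 before, although only 3910 were shared. The count does not tell how many of the 6092 calls came from the trend, since the same removal raised the count in the overexpression from 179 to 1334. A library difference that control cells also show is a candidate explanation for part of the pattern, since the knockdown fold changes correlated at r = 0.620 with the difference of MKN45 control replicate 2 from replicates 1 and 3, in libraries that share neither line nor treatment. An effect of lower ZNF165 cannot be told apart from it with these groups: knockdown replicate 1 deviated from the controls 0.640 times as much as replicates 2 and 3 (SD over genes 1.502 against 2.35 and 2.34), but its ZNF165 was also higher (4.75 CPM against 3.95 and 2.52). Knockdown replicates 2 and 3 are also the libraries whose descriptions name other genes in place of ZNF165, and whether their target differed was not tested.

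Fold changes in the arms were opposite across genes (r = −0.545), although they share no library. The r was −0.345 without MKN45 control replicate 2 and −0.238 with no filter. Against a length and GC trend as the whole cause, the correlation was −0.338 with the trend removed in both fits, beyond the bound of −0.2 set for it. The overexpression fold changes also correlated with the MKN28 control difference of replicate 2 from replicates 1 and 3 (r = −0.608), and with each arm regressed on the other line's control difference, GC content and length the correlation between arms was −0.194, between the bounds of −0.1 and −0.2. A library difference shared by control cells thus cannot be told apart, as the whole cause, from a shared response to ZNF165, which the design names and which was not tested separately.

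Among genes averaging at least 20 CPM over the 6 libraries of one line, 29 were listed at 0 in all 6 libraries of MKN28 and 23 in all 6 of MKN45, a stricter set than genes at 0 in the controls. Reads credited to an overlapping gene on the same strand were tested as a source: 2 of 49 protein-coding genes (4.08%, 95% interval 0.498 to 13.98%) overlapped another gene in that way, against 12.5% of 9726 other genes, a ratio of 0.326 with an upper limit of 1.12. That argues against such reads as the source for the set. Overlap on either strand was 40.8% against 54.4%. A lost or silenced gene in one line may account for such a value and stays open, as no DNA was measured. IFNL1, IFNL2 and IFNL3, at 0 in MKN45 and named after their values were seen, reached 20 CPM in MKN28 only through the knockdown libraries. They lay at 1.91 to 10.6 CPM in MKN28 controls and 77.9 to 238 CPM in the knockdown, scaled by TMM. As MKN45 had no knockdown, their 0 there says little of a lost or silenced gene.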

How the results depend on the processing

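Removal of the length and GC trend, library totals alone, and leaving out knockdown replicates 2 and 3 were chosen after seeing the data; the other alternatives were planned. The number of genes that differed between the control lines stayed within 1.5 times of 6717 under every alternative run (5085 to 8939). Of the other values that answer a comparison, those below lost their call or moved by more than 1.5 times, and the cause was not tested, except that fits with fewer libraries have less power by construction. Among single genes and lists, 1144 values kept direction and side of the threshold, 220 lost the call, 36 gained one and 13 reversed. Pseudocount and quantile alternatives were not run, as the values are counts. Depth limits genes near 3 counts, the level of 0.248 CPM by the unscaled total of the shallowest library.

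With knockdown replicates 2 and 3 left out, which leaves 1 knockdown library assumed to vary like the other groups, 3352 genes passed in the knockdown (2730 of them among the 6092), 1217 differed between arms, 41 moved with ZNF165 in both arms and 8 lists were called in the knockdown. In the overexpression 722 genes passed with no filter, 1334 with the trend removed, 3 in the fit of all 12 libraries and 1834 with DESeq2, against 179. DESeq2 gave 4730 genes differing between arms. Genes that moved with ZNF165 in both arms numbered 356 with no filter, 512 with the trend removed, 2 in the fit of all 12 libraries and 968 with DESeq2, against 69. With the correlation estimated per list camera called 0 lists in the knockdown and 0 in the overexpression, against 4 and 9 with the preset correlation, and fry called 10 and 2. With the replicate number as a block, although the numbers did not pair the treated libraries with their controls, 8 genes passed in the overexpression, 2 moved in both arms, and ZNF165 in the knockdown had a log2 fold change of −1.48 (adjusted p = 0.0643, edgeR quasi-likelihood test).

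ZNF165 in the knockdown also lost its call with no filter (−1.54, adjusted p = 0.0703, edgeR quasi-likelihood test) and with knockdown replicates 2 and 3 left out (−1.09, adjusted p = 0.198), where adjusted p over all alternatives lay between 0.00715 and 0.198. With single libraries left out, the count in the knockdown was 2642 (without control replicate 1) to 10378 (without knockdown replicate 1), and in the overexpression 1 (without overexpression replicate 1 or 2) to 1338 (without control replicate 2). Between arms it was 1163 (without MKN45 control replicate 1) to 8210 (without knockdown replicate 1) and in both arms 0 (without overexpression replicate 1 or 2) to 637 (without MKN45 control replicate 2), and the lists called were 3 to 7 in the knockdown and 8 to 12 in the overexpression. The log2 fold change of ZNF165 was −1.63 to −1.23 in the knockdown and 2.88 to 3.45 in the overexpression.

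Signs reversed for CD274, B2M and CXCL10, which had not passed, and for ZNF696, which had. CD274 in the knockdown was 1.87 with the trend removed (past the threshold, adjusted p = 0.0191, edgeR quasi-likelihood test), −0.25 with library totals alone and −0.19 to 1.46 with single libraries left out, and in the overexpression −0.0457 to 1.03. B2M in the knockdown was −0.28 with the replicate block and −1.16 (without knockdown replicate 1, past the threshold with adjusted p = 0.0137, edgeR quasi-likelihood test) to 1.33 with single libraries left out, and 2.21 (adjusted p = 0.00777) with replicate 1 as the lone knockdown library. CXCL10 in the knockdown was −0.0426 with upper-quartile factors, −0.0117 with no filter, −2.61 with the replicate block (past the threshold, adjusted p = 0.0477, edgeR quasi-likelihood test), −0.18 with the trend removed, −0.39 with library totals alone, and −8.71 to 0.62 with single libraries left out (−0.13 without control replicate 2). The value of −8.71, without knockdown replicate 1, passed (adjusted p = 0.000175, edgeR quasi-likelihood test) against a knockdown group at 0 counts and gives no size of the change. ZNF696 was −0.26 with knockdown replicates 2 and 3 left out.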

Other observations

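The genes of this part, its tests of a nuclear-retained list and its test of neighbouring silent genes were all chosen after their values were seen.

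Interferon genes themselves were higher in all 3 knockdown libraries of MKN28. IFNL1, which encodes a type III interferon of epithelial cells, had 5.75, 10.6 and 2.38 CPM in the controls and 77.9, 180 and 160 CPM in the knockdown (log2 fold change 4.47, SE 0.68). IFNL2 (4.55, SE 0.54) and IFNL3 (5.27, SE 0.66) are close copies of each other, so their reads could be shared; IFNB1, the main type I interferon of non-immune cells, had a log2 fold change of 4.63 (SE 0.74). All 4 had adjusted p of 0.00367 to 0.00370 (edgeR quasi-likelihood test), and passed with the length and GC trend removed (2.86 to 4.35, adjusted p of 0.000896 to 0.00168). With replicate 1 as the lone knockdown library, a fit whose spread is taken from the controls, they had log2 fold changes of 3.65 to 5.59. Genes that answer to interferon did not move as one. ISG15, a ubiquitin-like protein, rose by 3.40, while OAS1, a sensor of double-stranded RNA, fell (log2 fold change −2.42). IFIT1 and IFIT2, which bind foreign RNA, did not pass (0.18 and 1.35, adjusted p = 0.904 and 0.180, edgeR quasi-likelihood test). IFIT2 passed as a rise with the trend removed (2.22, adjusted p = 0.00442), and IFIT1 passed as a fall without knockdown replicate 1 (−3.12, adjusted p = 2.96e-05, edgeR quasi-likelihood test). With replicate 1 as the lone knockdown library both passed as a rise (1.70 for IFIT1 and 2.64 for IFIT2, adjusted p = 0.0183 and 0.00678, edgeR quasi-likelihood test). IFIT1 lay at 530 CPM in knockdown replicate 1 against 21.3 and 13.7 in replicates 2 and 3 and 139 to 196 in the controls.

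Of the genes that passed in both arms with opposite signs, MALAT1 and NEAT1, long non-coding RNAs kept in the nucleus, had log2 fold changes of −4.78 and −3.95 in the knockdown and 1.41 and 1.77 in the overexpression. PNN and SRRM2, proteins of nuclear speckles, had −2.35 and −1.65 in the knockdown and 1.87 and 1.44 in the overexpression, and CENPE and ASPM, which act at the kinetochore and the spindle pole, −4.32 and −3.39, and 2.53 and 2.07. The list of mitotic genes passed camera in neither arm: 5 of 30 rose and 9 fell in the knockdown (median −0.70, adjusted p = 0.262), and 1 of 30 rose and 0 fell in the overexpression (median 0.24, adjusted p = 0.127). CDKN1A rose in both arms (2.78 and 1.17), and CTNND1, the p120 catenin, fell in both (−2.66 and −1.13).

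A difference in the nuclear share of the RNA between libraries was tested as a hypothesis, with a list of 27 nuclear-retained or detained-intron transcripts. It was set against 10000 random lists matched on abundance, length and GC content. Abundance was that of the MKN28 libraries throughout, so the MKN45 comparisons were not matched on the level in their own line. In the knockdown the list's median of −1.03 lay at percentile 65.8 of the matched lists (mean −1.18, 95% range −1.94 to −0.43), which argues against that difference beyond the trend of length and GC content. In the overexpression the 23 members outside the genes that passed in both arms had a median of 0.82, at percentile 100 of the matched lists (mean 0.22, 95% range −0.01 to 0.47). A larger nuclear share there may be one candidate explanation. The list was chosen after values were seen, and the 23 still held DDX5 and SRSF6, which passed in the overexpression, so the percentile is no independent support. Of all 27 members 6 rose and 0 fell in the overexpression, and 2 rose and 12 fell in the knockdown. Control libraries differed in the list too: for replicate 2 minus replicates 1 and 3 the median of all 27 members was −1.25 in MKN28, at percentile 0 of the matched lists (mean −0.55, 95% range −0.79 to −0.28), and −0.66 in MKN45, at percentile 53.2. A library difference without treatment thus stays open for the overexpression value, and a change in transcription or decay was not tested.

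Neighbouring genes were silent together in one line. At 16p13.3 MPG, a DNA repair glycosylase, had 120 CPM over the 6 libraries of MKN28 and 0.00867 CPM over those of MKN45, NPRL3, a regulator of mTORC1, 45.9 and 0, LUC7L, a splicing factor, 25.7 and 0, and FAM234A 105 and 0.0373, while RHBDF1 on one side (59.9 and 48.7) and AXIN1 on the other (134 and 24.1) were present in both. Genes with at least 5 CPM in one line and at most 18 counts over the 6 libraries of the other were taken as silent there, 163 in MKN45 and 427 in MKN28. The 12556 genes with at least 5 CPM in either line gave 9 runs of at least 3 silent neighbours over both lines. Several of these runs held clustered gene families. A run of 6 in MKN45 held SPRR genes and S100A9, a run of 5 there MAGEA and CSAG genes, and a run of 6 in MKN28 UGT1A genes. A run of 4 in MKN45 arose in 3 of 10000 shuffles of the 12556 genes, which argues against chance placement. The shuffles treated neighbours as unrelated, so a family of neighbouring genes that is silent together gives such a run too. They thus decide nothing on why the genes at 16p13.3 were silent. At 9p21 IFNB1, KLHL9, MTAP and the tumour suppressor CDKN2A (83.1 CPM in MKN28) had 0 counts in every MKN45 library. IFNB1 reached 5 CPM in MKN28 only through the knockdown libraries (56.5, 16.2 and 16.3 CPM scaled by TMM, against 1.61, 1.27 and 0.693 in the controls). Its 0 in MKN45, which had no knockdown, thus says little of a lost or silent gene. A deletion may account for the runs at 16p13.3 and 9p21, as may silencing, and neither was tested since no DNA was measured.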
